A study of Rattus norvegicus with 28 samples.

How the data were processed

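The series holds 28 Affymetrix arrays of male rats, hybridized with biotin-labelled cRNA after 1 cycle of amplification. Hearts had been grafted into the neck of the recipient with a cuff technique, and the cells had been separated with magnetic beads. The deposited values are log2 signals per probe set that the authors made with RMA in the affy package (background correction, quantile normalization and median-polish summary), with versions not given in the sources used here. From the values, the 24 endothelial arrays had been normalized together (medians 6.51 to 6.59) and the 4 leukocyte arrays apart from them (medians 6.83 to 6.88). The values were used as they stood. Every data column belonged to a sample, with 0 columns left over. Samples were grouped by the labels into normal DA endothelium, normal Lewis endothelium, allografts and isografts of days 2, 3 and 4 (3 arrays each), and leukocytes of days 2, 3 and 4 (1, 2 and 1 arrays). The series calls the 3 arrays of a group biological replicates; whether each came from 1 animal is not given in the sources used here.

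Of 31099 probe sets, 57 controls, 436 that matched several genes and 9780 not listed in the gene annotation used here were left out, and 20826 matched a single gene. Of these, 20758 had an Entrez identifier in the RefSeq list from which symbols were taken. Of several probe sets of a gene (4525 genes) the one with the highest mean over the endothelial arrays was kept, which gave 14217 genes, with no filter on dim genes. limma 3.58.1 (lmFit and eBayes with a constant prior, in R 4.3.3, with version 1.17.8 of data.table) was fitted to the 24 endothelial arrays with 1 mean per group, 16 residual degrees of freedom and a prior worth 4.06. In each of 13 comparisons the p-values were adjusted over all genes after Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. The comparisons were DA against Lewis normal endothelium, each day of isografts against Lewis and of allografts against DA normal endothelium, the difference of both changes per day, day 4 against day 2 in each graft type, and the difference of these. On simulated data, 83% and 98% of 100 genes changed by 1 and 2 log2 were recovered in the day 4 allograft comparison and 59% and 94% in the day 4 difference of changes, with 8 false calls in each comparison of 14217 genes. The simulated noise was independent between genes and had the same spread in every group, and many genes were changed together. Recovery of a lone gene, or in groups with a larger spread, may be lower. Array signals have no counting depth, and their number limits the precision.

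Gene lists numbered 30, of which 17 named processes and 13 cell types, with 460 members fixed and 405 measured. The process lists were interferon-gamma-induced, type I interferon-induced, MHC class I and processing, MHC class II, leukocyte adhesion, chemokines, NF-kB inflammatory genes, complement, coagulation and fibrinolysis, vasoregulation, angiogenesis and Notch, lipid uptake of cardiac capillaries, hypoxia and glycolysis, oxidative and heat stress, proliferation, extracellular matrix, and cell death. The cell type lists were endothelial, pan-leukocyte, T cell, cytotoxic lymphocyte, B cell, macrophage, neutrophil, cardiomyocyte, fibroblast, mural, lymphatic endothelium, erythroid and platelet. For each list the called members were counted, over all genes and adjusted over the list alone, and limma's camera was run with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. A list is said to have passed where both settings gave an adjusted p under 0.05, or with the preset correlation only where it says so. These words concern camera alone. Beside it fry was run, which tests a list by itself. At an adjusted p under 0.05 fry passed 4, 10 and 10 of the 30 lists in isografts on days 2, 3 and 4 and 14, 12 and 23 in allografts. It passed 1 list for strain, 0 in each difference of changes per day, and 1, 7 and 0 between day 2 and day 4 for isografts, allografts and their difference. Named were genes with 1 symbol: of those called in 1 direction on all 3 days the 8 highest and 6 lowest per graft type, per day the 3 highest and 2 lowest called, for the strain and time comparisons the 6 highest and 6 lowest called, for leukocytes the 8 highest and 8 lowest, and of each list up to 4 members with the largest difference. The comparisons, the test, the lists, the rule for named genes and the alternatives listed last were fixed before the data were examined.

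The leukocyte comparison had been planned as a limma test on all arrays. It was replaced, after the data were seen, by a comparison of levels, since the leukocyte arrays had been normalized separately and such a test cannot part the cell type from the normalization. The median difference of 0.334 log2 between both sets was removed, and a gene counted as higher in leukocytes or endothelium at 2-fold or more with no overlap between the 4 leukocyte and the 9 allograft endothelial arrays. Overlaps between days were set against independent lists, and against 20 simulations without change that were run for the allograft comparisons. The replicate numbers were tested as pairs. In day 2 isografts against Lewis normal hearts the paired arrays had r of 0.292 to 0.412 after removal of the group means and each was nearest to its own number (6 of 6). With the number as a block 255 genes were called instead of 211, and leukocyte adhesion was still called (adjusted p = 0.0228 with an estimated correlation). Alternatives were centring on the medians, quantile normalization of all 28 arrays, leaving out the 30% of genes with the lowest means, the mean of a gene's probe sets or every probe set, a trended robust prior, array weights, a 2-fold minimum, the compared groups alone, all 28 arrays, the replicate block, the direct difference of the grafts, and leaving out strain-different genes, leukocyte-enriched genes or 1 array at a time. Added after the data were seen were a fit without the 2 allograft arrays richest in fibroblast transcripts, 1 with the mean of the pan-leukocyte genes as a covariate, and 1 with array weights estimated gene by gene, since the default estimate stopped before it converged. Other splits of the samples were counted for each comparison, at most 100. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.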

Results

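RNA of endothelial cells from rat hearts was measured on 24 Affymetrix arrays in 8 groups of 3. The groups were normal hearts of DA rats, normal hearts of Lewis rats, DA hearts grafted into Lewis recipients (allografts, mismatched for transplantation antigens) and Lewis hearts grafted into Lewis recipients (isografts, matched), with grafts taken on days 2, 3 and 4. Endothelial cells, which line the vessels, came from minced hearts after removal of cells carrying the leukocyte protein CD45 and collection of cells carrying CD31. Leukocytes of allografts were measured on 4 further arrays, 1 from day 2, 2 from day 3 and 1 from day 4. The deposited log2 signals had medians of 6.51 to 6.59 over the endothelial arrays and of 6.83 to 6.88 over the leukocyte arrays. Replicates of a group correlated with r = 0.969 (allograft day 4) to 0.994 (isograft day 3) across genes, which are not independent of each other. The number of arrays limits the precision, and the standard error (SE) of a difference between 2 groups had a median of 0.165 log2 over 14217 genes. Every group had n = 3, and the p-values measure only the spread between samples.

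Isografts were compared with Lewis normal endothelium to ask what transplantation did to vessel lining cells when donor and recipient were matched. Endothelial preparations of isografts gained the transcripts with which vessels catch leukocytes. P-selectin (Selp), which makes leukocytes roll along the vessel wall, rose by 3.88, 4.23 and 3.83 log2 on days 2, 3 and 4 (SE 0.44, adjusted p at most 3.35e-05). E-selectin (Sele), which has the same task, rose by 3.36, 3.68 and 3.57 log2 (SE 0.38). The chemokine-binding receptor of venules Ackr1 rose by 2.81, 2.13 and 2.40 log2, and the adhesion receptor Vcam1 by 1.76, 1.82 and 1.62 log2. At the same time transcripts of macrophages, the tissue phagocytes, came up in these preparations, with Gpnmb higher by 4.93, 4.98 and 5.97 log2 (SE 0.48) and lysozyme (Lyz2) by 2.86, 3.80 and 4.17 log2. Lower among transcripts of heart muscle cells were the atrial-type myosin heavy chain Myh6 at -2.19, -2.40 and -2.14 log2 (SE 0.40) and myoglobin (Mb), the oxygen store of muscle, at -1.92, -2.12 and -2.06 log2.

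Of the 15 leukocyte adhesion genes measured in isografts, 5, 4 and 5 rose on days 2, 3 and 4 and 0 fell (7, 6 and 6 rose and 2, 1 and 0 fell adjusted over the list alone). Their medians were 0.41, 0.22 and 0.15 log2. The group passed on each day (adjusted p = 0.00708, 0.0263 and 0.0241 with an estimated correlation). Of 8 complement genes, which tag targets for phagocytes, 2, 3 and 4 rose and 0 fell on each day (4, 4 and 5 rose adjusted over the list alone). Their medians were 0.72, 0.78 and 0.92 log2. The complement group passed on days 3 and 4, and on day 2 it passed with the preset correlation only (adjusted p = 0.0753, 0.0485 and 0.0253 with an estimated correlation). Its risers were the anaphylatoxin receptor C5ar1 at 1.79, 2.38 and 2.95 log2, the C1 inhibitor Serping1 at 1.64, 1.79 and 1.79 log2, and Cd55, a shield against complement, at 1.40 log2 on day 3 (adjusted p = 0.0265). Among 20 chemokines, the signals that attract leukocytes, 3, 5 and 5 rose and 0 fell on each day (3, 6 and 6 rose adjusted over the list alone). The chemokine group passed with the preset correlation only (adjusted p = 0.318, 0.175 and 0.203 with an estimated correlation). Ccl2 and Ccl7, which attract monocytes, rose by 2.27, 2.48 and 2.68 and by 2.63, 3.08 and 3.40 log2, and Cxcl2, which attracts neutrophils, by 2.21, 3.17 and 3.61 log2. Inflammatory genes driven by the transcription factor NF-kB numbered 18, of which 1, 3 and 3 rose and 0 fell on each day (3, 5 and 5 rose and 1, 0 and 0 fell adjusted over the list alone; adjusted p = 0.329, 0.186 and 0.351 with an estimated correlation). The prostaglandin-producing enzyme Ptgs2 rose by 3.08, 3.73 and 3.20 log2, and the cytokine Il1b by 3.03 and 3.24 log2 on days 3 and 4.

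Transcripts of vessel structure and matrix changed in isografts in single genes, and no list of them passed with an estimated correlation. Plvap, the protein of the diaphragms of leaky vessels, rose by 2.42, 2.38 and 2.61 log2, and Adamts4, a protease of the matrix, by 3.49, 3.61 and 3.58 log2. Angpt2, a destabilizer of vessels, rose by 0.96, 1.47 and 0.97 log2. Esm1, a transcript of sprouting endothelium, stood at -2.37, -1.27 and -1.46 log2 and passed on day 2 only (adjusted p = 0.00580, 0.174 and 0.0876). Of 21 extracellular matrix genes, 2, 5 and 9 rose and 0 fell on each day (6, 6 and 10 rose adjusted over the list alone; adjusted p = 0.262, 0.25 and 0.172 with an estimated correlation). The matrix protein of healing tissue Postn rose by 5.64 log2 on day 4 (SE 1.03, adjusted p = 0.00251), and collagen Col1a1 by 4.72 log2. Of 18 cardiomyocyte genes, 4, 8 and 7 fell and 0 rose on each day (11, 11 and 10 fell adjusted over the list alone). Their medians were -0.83, -1.08 and -1.01 log2 (adjusted p = 0.167, 0.130 and 0.147 with an estimated correlation). Lymphatic markers were 4, of which 2 rose on each day (adjusted p of the list = 0.193, 0.131 and 0.210 with an estimated correlation; 2, 3 and 3 rose adjusted over the list alone). Lyve1 rose by 2.37, 2.46 and 2.39 log2 and Pdpn by 2.91, 2.85 and 2.74 log2. The lymphatic regulator Prox1 had values of 0.93, 1.10 and 1.08 log2 and did not pass (adjusted p = 0.503, 0.283 and 0.267). Of 14 interferon-gamma-induced genes, 0, 1 and 1 rose (1, 1 and 1 adjusted over the list alone; adjusted p = 0.775, 0.457 and 0.563 with an estimated correlation). The gene that rose was the T cell chemokine Cxcl11, by 3.38 and 2.80 log2 on days 3 and 4. Markers shared by endothelial cells numbered 18, of which 1 rose on each day, namely Plvap, and 0 fell on each day. The endothelial medians were -0.07, -0.07 and -0.09 log2 against positive means of 0.10, 0.07 and 0.06 log2, and the test pointed up on day 2 and down on days 3 and 4 (adjusted p = 0.877, 0.977 and 0.821 with an estimated correlation).

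Macrophage transcripts rose broadly in the isograft preparations. Of 18 genes, 8, 15 and 16 rose and 0 fell on each day (11, 17 and 17 rose adjusted over the list alone). Their medians were 1.66, 2.34 and 3.04 log2. The mannose receptor Mrc1 rose by 2.62, 3.09 and 3.83 log2. The list passed on days 3 and 4, and on day 2 with the preset correlation only (adjusted p = 0.0840, 0.0263 and 0.0154 with an estimated correlation). All 18 of its genes were at least 2-fold higher in graft leukocytes than in allograft endothelium, and so were 1 of the adhesion genes, 3 of the complement genes and 7 of the chemokines. Of 17 pan-leukocyte genes, 1, 4 and 6 rose (4, 10 and 11 adjusted over the list alone; adjusted p = 0.317, 0.130 and 0.147 with an estimated correlation). Cd53, a surface protein of leukocytes, rose by 1.91, 2.77 and 3.25 log2. Ptprc, which encodes CD45, rose by 2.02 and 2.26 log2 on days 3 and 4. T cell genes numbered 15, of which 1, 1 and 4 rose (1, 1 and 5 adjusted over the list alone; adjusted p = 0.615, 0.358 and 0.563 with an estimated correlation). The T cell kinase Lck rose by 0.92, 0.81 and 1.04 log2. Of 7 MHC class II genes, which present antigen to helper T cells, 0, 2 and 5 rose (1, 5 and 6 adjusted over the list alone; adjusted p = 0.354, 0.130 and 0.126 with an estimated correlation). RT1-Da, a class II chain, rose by 2.12 and 2.52 log2 on days 3 and 4.

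By limma, 211 genes passed in isografts on day 2 (151 higher and 60 lower), 360 on day 3 (256 and 104) and 450 on day 4 (371 and 79). On all 3 days 134 genes were higher and 34 were lower, against 0.0710 and 0.00244 for independent lists. In 20 simulations without change, run for the allograft comparisons, 0 genes were called on all 3 days. Data without change give hardly any calls on a single day, so these simulations cannot show what shared controls do. The days share their 3 normal hearts, which are too few to split, so part of the excess over independent lists may come from the shared controls. Genes at least 2-fold higher in graft leukocytes made up 51 of the 151 higher genes on day 2 (33.8%), 119 of 256 on day 3 (46.5%) and 192 of 371 on day 4 (51.8%), against 8.64% of all genes. With the mean of the pan-leukocyte genes as a covariate 65, 41 and 34 genes passed. The day 2 count was 127 without Lewis normal replicate 1, 136 without Lewis normal replicate 2 and 92 without day 2 replicate 2. The day 3 count was 177 and 186 without these Lewis normal replicates and 150 and 178 without day 3 replicates 2 and 3, and the day 4 count was 256 and 299 without Lewis normal replicates 2 and 3 and 246 and 260 without day 4 replicates 1 and 3. With an estimated correlation the adhesion group no longer passed on day 3 without day 3 replicate 1 (adjusted p = 0.0822) or on day 4 without day 4 replicate 1 (0.0565), nor the complement group on day 3 without Lewis normal replicate 1 (0.106), Lewis normal replicate 2 (0.0634) or day 3 replicate 1 (0.0822) and on day 4 without Lewis normal replicate 1 (0.113) or day 4 replicate 1 (0.0603).

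**Figure D1:**
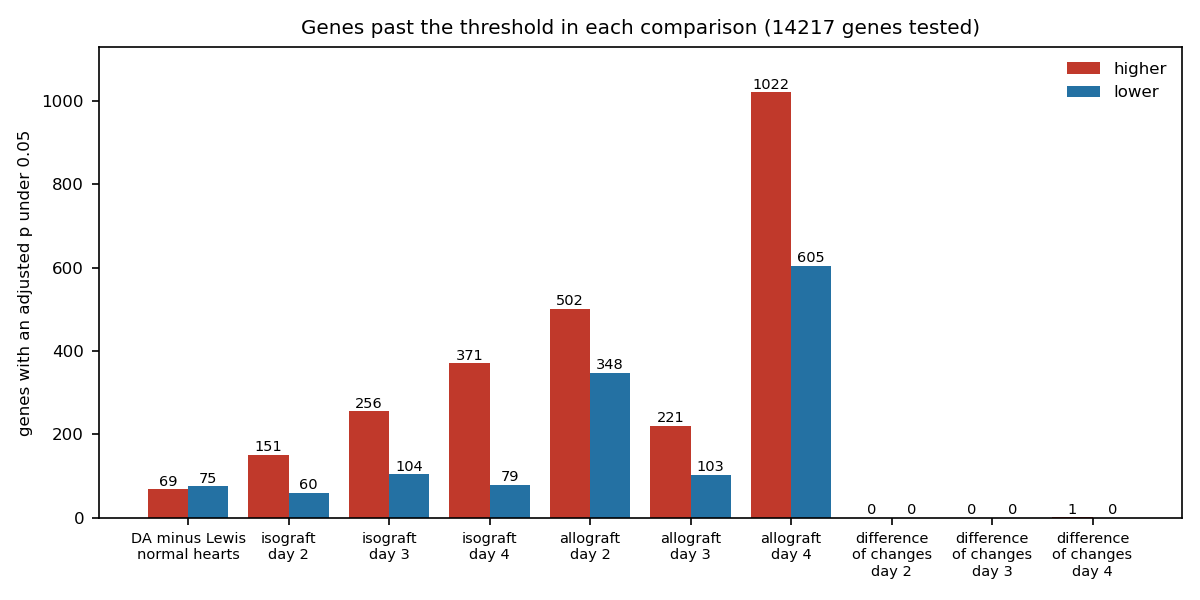
Paired bars give the number of genes (vertical axis) higher and lower at an adjusted p under 0.05 by limma in each comparison, for normal hearts of both strains, isografts and allografts by day, and the difference between the changes of both graft types. Isografts went from 211 genes on day 2 to 450 on day 4, allografts from 850 to 324 and then 1627, and the differences of changes held 0, 0 and 1 genes.

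Allografts were compared with DA normal endothelium to ask how vessel lining cells of a mismatched heart changed while rejection set in. Allograft preparations gained MHC class II, complement, macrophage and pan-leukocyte transcripts as groups, and single chemokines that interferon-gamma induces. RT1-Da, an MHC class II chain, rose by 3.37, 3.97 and 4.79 log2 on days 2, 3 and 4 (SE 0.45, adjusted p at most 9.51e-05). Cxcl11, an interferon-gamma-induced chemokine for activated T cells, rose by 3.80, 5.89 and 6.83 log2 (SE 0.70, adjusted p at most 0.00194). Ido1, the tryptophan-degrading enzyme that restrains T cells, rose by 3.83 log2 on day 3 and 5.39 log2 on day 4 (SE 0.73). Among the largest rises on all 3 days were the phagocyte genes Gpnmb at 6.10, 4.36 and 5.66 log2 and Lyz2 at 4.70, 4.13 and 4.72 log2. Esm1 fell, to -2.60, -1.96 and -2.11 log2 (SE 0.45), as did Smad9, a transducer of bone morphogenetic protein signals, to -1.72, -1.62 and -1.68 log2.

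Of the 7 MHC class II genes, 6 rose on each day and 0 fell (6 rose on each day adjusted over the list alone). Their medians were 2.40, 3.04 and 3.87 log2 (adjusted p = 0.0318, 0.00721 and 0.0200 with an estimated correlation). The invariant chain Cd74, which guides class II molecules, rose by 2.47, 3.27 and 4.09 log2, and RT1-Bb by 2.97, 3.56 and 4.57 log2. In graft leukocytes 6 of these 7 genes were at least 2-fold higher than in allograft endothelium. Of 14 interferon-gamma-induced genes, 1, 5 and 9 rose and 1, 0 and 0 fell (1, 8 and 11 rose and 2, 0 and 0 fell adjusted over the list alone). Their medians were 0.27, 1.13 and 1.95 log2. On days 3 and 4 this group passed camera with the preset correlation only (adjusted p = 0.986, 0.0712 and 0.0879 with an estimated correlation). By fry its adjusted p was 0.808, 0.0121 and 0.000126 on days 2, 3 and 4. In graft leukocytes 1 of its genes was at least 2-fold higher. Cxcl9, another chemokine for activated T cells, rose by 2.72 and 3.27 log2 on days 3 and 4, and Cxcl10 by 3.73 log2 on day 4 (adjusted p = 0.00126). MHC class I and antigen processing genes numbered 16, of which 0, 0 and 6 rose (0, 0 and 10 adjusted over the list alone; adjusted p = 0.514, 0.310 and 0.189 with an estimated correlation). The peptide transporter Tap1 and the class I regulator Nlrc5 rose by 1.75 and 1.75 log2 on day 4. Of 21 type I interferon-induced genes, the antiviral program, 12, 0 and 0 fell on days 2, 3 and 4 and 0 rose (18, 0 and 0 fell adjusted over the list alone). Their medians were -1.23, -0.26 and -0.15 log2. The antiviral factors Mx2 and Usp18 fell on day 2, to -2.16 and -1.82 log2. The group passed on days 2 and 3 with the preset correlation only (adjusted p = 0.0804, 0.570 and 0.871 with an estimated correlation).

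Leukocyte adhesion genes rose in allografts too, 6, 4 and 5 of 15 on days 2, 3 and 4, while 1, 0 and 2 fell (7, 5 and 5 rose and 2, 1 and 3 fell adjusted over the list alone). Selp rose by 3.55, 2.81 and 3.54 log2 and Sele by 2.39, 1.85 and 2.53 log2. The group passed on day 3, on the other days with the preset correlation only (adjusted p = 0.0730, 0.0308 and 0.0933 with an estimated correlation). Of the 8 complement genes, 2, 4 and 6 rose and 0 fell on each day (7, 6 and 6 rose adjusted over the list alone). Their medians were 1.03, 1.38 and 2.19 log2 (adjusted p = 0.0318, 0.00721 and 0.0200 with an estimated correlation). Serping1 rose by 1.45, 2.16 and 3.18 log2, the complement protease C1s by 2.46 and 3.35 log2 on days 3 and 4, and the central component C3 by 2.28 log2 on day 4. Chemokine genes that rose were 6, 5 and 10 of 20, and 1, 0 and 1 fell (8, 8 and 10 rose and 1 fell on each day adjusted over the list alone; adjusted p = 0.162, 0.0712 and 0.0879 with an estimated correlation). Ccl7 rose by 2.76, 2.26 and 3.15 log2. NF-kB genes that rose were 4, 1 and 4 of 18, and 1, 0 and 1 fell (5, 3 and 8 rose and 1 fell on each day adjusted over the list alone; adjusted p = 0.514, 0.517 and 0.244 with an estimated correlation). The antioxidant enzyme Sod2 rose by 1.59 and 2.35 log2 on days 2 and 4, and the cytokine Tnf fell by 1.79 log2 on day 2. Angiogenesis and Notch genes leaned down: of 17 genes measured, 4, 2 and 6 fell and 2 rose on each day (8, 4 and 8 fell and 2 rose on each day adjusted over the list alone). Their medians were -0.66, -0.37 and -0.52 log2. That group passed on day 2, and later with the preset correlation only (adjusted p = 0.0318, 0.0712 and 0.0879 with an estimated correlation). Its members that fell included the guidance receptor Unc5b at -1.08 log2 on day 2 and the apelin receptor Aplnr at -1.64 log2 on day 4. The vessel growth factors Angpt2 and Pgf rose by 1.59, 1.18 and 1.77 and by 2.01, 1.63 and 2.27 log2. Shared endothelial markers numbered 18, of which 1, 0 and 3 fell and 1 rose on each day (6 fell and 1 rose on day 4 adjusted over the list alone; adjusted p = 0.297, 0.517 and 0.0879 with an estimated correlation). The VEGF receptor Kdr fell, to -1.04 and -0.60 log2 on days 2 and 4, and Plvap rose by 1.98, 1.69 and 2.10 log2.

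Of the 18 macrophage genes, 17, 15 and 18 rose and 0 fell on each day (17, 18 and 18 rose adjusted over the list alone). Their medians were 2.91, 2.29 and 3.29 log2 (adjusted p = 0.0318, 0.00721 and 0.0200 with an estimated correlation). Pan-leukocyte genes that rose were 14, 11 and 14 of 17 (15, 14 and 14 adjusted over the list alone; adjusted p = 0.0318, 0.0144 and 0.0300 with an estimated correlation). Among these, Ptprc rose by 2.82, 2.93 and 3.47 log2. Of 15 T cell genes, 3, 8 and 14 rose (13, 14 and 15 adjusted over the list alone). The list passed on day 3, on the other days with the preset correlation only (adjusted p = 0.162, 0.0308 and 0.0762 with an estimated correlation). The T cell receptor chain Cd3g rose by 2.00, 2.33 and 3.18 log2, and the killer T cell marker Cd8a by 1.88, 1.86 and 2.67 log2. Of 11 cytotoxic lymphocyte genes, 0, 2 and 6 rose (1, 8 and 10 adjusted over the list alone; adjusted p = 0.542, 0.0712 and 0.180 with an estimated correlation). Granzyme A (Gzma), a protease of killer cells, rose by 2.20 and 2.15 log2 on days 3 and 4. Of 11 neutrophil genes, 5, 0 and 1 rose (7, 0 and 1 adjusted over the list alone; adjusted p = 0.0804, 0.274 and 0.295 with an estimated correlation). S100a9, an alarm protein of neutrophils, rose by 3.86 log2 on day 2. Of 21 extracellular matrix genes, 5, 1 and 10 rose (5, 5 and 12 adjusted over the list alone; adjusted p = 0.271, 0.517 and 0.189 with an estimated correlation). Postn rose by 3.72 and 4.85 log2 on days 2 and 4. Fibroblast transcripts differed between replicates of a day, with list means of 0.52 ± 1.28 log2 on day 2 (-0.49 to 1.97) and 0.99 ± 1.22 log2 on day 4 (-0.16 to 2.27, SD, n = 3) over DA normal hearts. Cardiomyocyte genes gave 2, 0 and 3 falls and 0, 1 and 0 rises of 18 (2, 0 and 5 fell and 0, 1 and 0 rose adjusted over the list alone; adjusted p = 0.514, 0.815 and 0.354 with an estimated correlation).

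By limma, 850 genes passed in allografts on day 2 (502 higher and 348 lower), 324 on day 3 (221 and 103) and 1627 on day 4 (1022 and 605). On all 3 days 182 genes were higher and 77 lower, against 0.561 and 0.107 for independent lists and 0 in 20 simulations without change. The same reservations hold about these simulations and about the shared normal hearts. Genes at least 2-fold higher in graft leukocytes were 267 of the 502 higher genes on day 2 (53.2%), 138 of 221 on day 3 (62.4%) and 423 of 1022 on day 4 (41.4%). Leaving such genes out gave 494 genes on day 2 (204 higher and 290 lower), 121 on day 3 (63 and 58) and 1095 on day 4 (551 and 544). With arrays centred on their medians, 434 were higher and 426 lower on day 2. With the mean of the pan-leukocyte genes as a covariate, which moves almost in step with graft against normal, 3, 1 and 0 genes passed. The day 2 count was 440 and 485 without DA normal replicates 2 and 3 and 421 without day 2 replicate 3. The day 3 count was 180 and 197 without those normal replicates and 168 without day 3 replicate 2, and the day 4 count was 1002 and 1027 without them, 2606 without day 4 replicate 1 and 862 without day 4 replicate 3. With an estimated correlation, the day 2 calls of the MHC class II, complement, angiogenesis and pan-leukocyte groups were lost without DA normal replicate 1 (adjusted p = 0.0655, 0.0810, 0.0810 and 0.0677), without day 2 replicate 2 (0.0583, 0.0783, 0.0583 and 0.0583) and without day 2 replicate 3 (0.0665, 0.0665, 0.0947 and 0.0665), and that of the macrophage list without DA normal replicate 1 (0.0655) and day 2 replicate 3 (0.0578). The day 3 call of adhesion was lost without DA normal replicate 1 (0.0665) and day 3 replicate 1 (0.0729), and the day 3 call of T cell genes without DA normal replicates 1 and 3 (0.0612 and 0.0513) and day 3 replicates 2 and 3 (0.0663 and 0.0581).

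**Figure D2:**
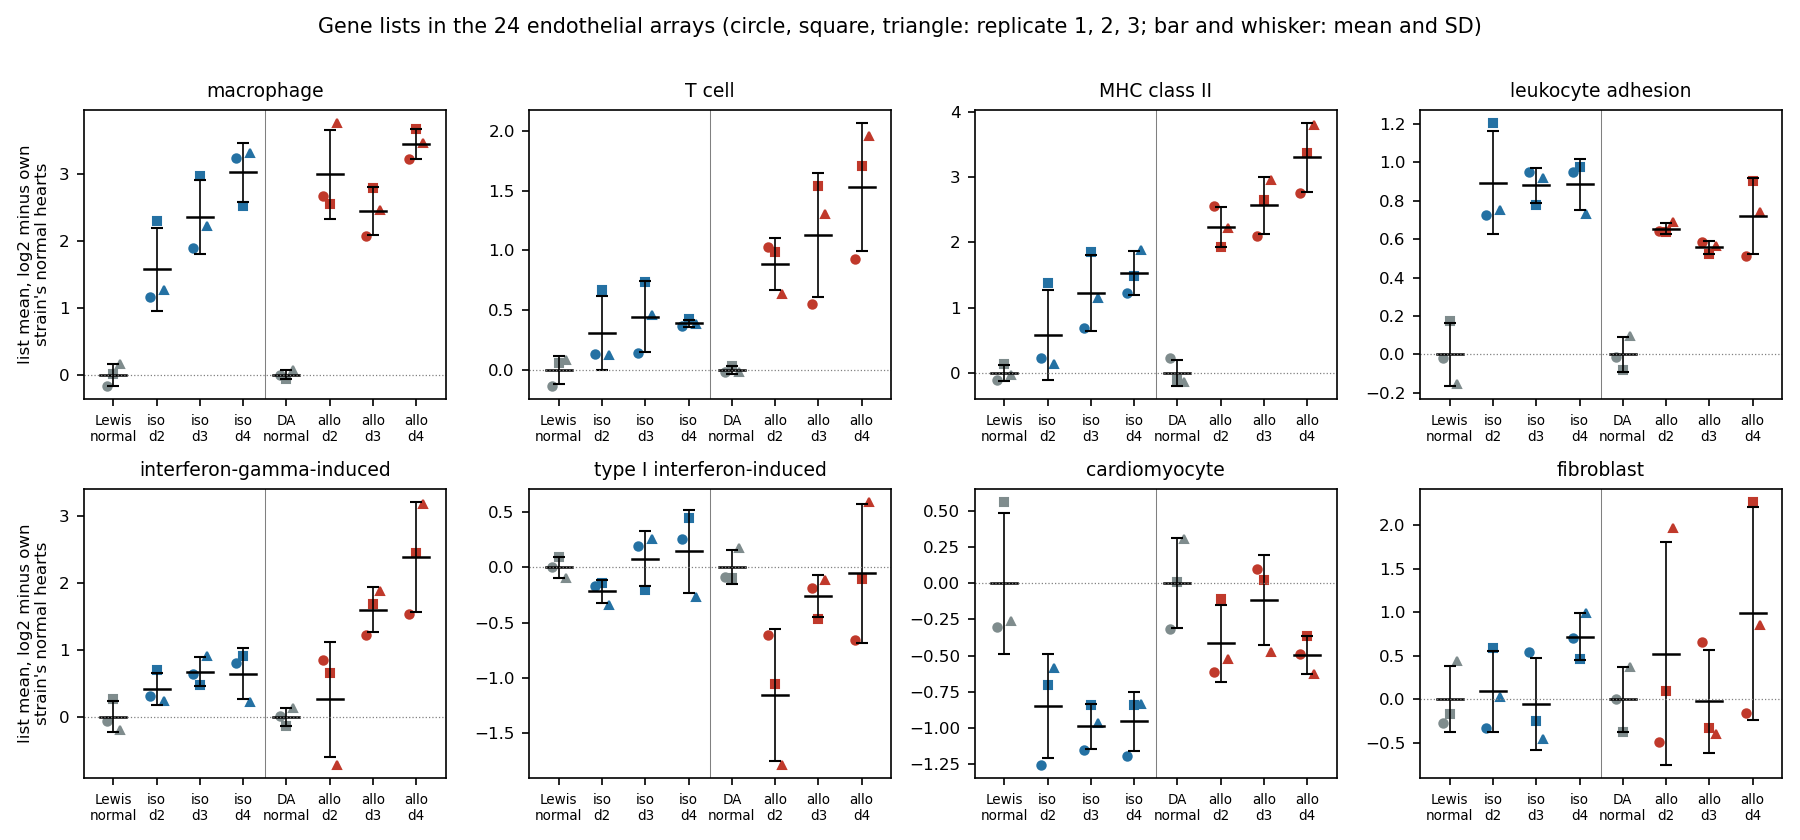
Each panel shows 1 gene list, with the mean of its genes per array minus the mean of the own strain's normal hearts (log2) for normal hearts and days 2, 3 and 4 of isografts and allografts. Circles, squares and triangles are replicates 1, 2 and 3, bars are means and whiskers are SD (n = 3), and the interferon-gamma list of allografts goes from 0.26 on day 2 to 2.39 on day 4.

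To ask which changes belong to the mismatch, the change in allografts was set against the change in isografts of the same day. Sectm1b, a member of a family of secreted immune cell ligands, was the gene whose change differed: on day 4 its rise was 3.35 log2 larger in allografts than in isografts (SE 0.37, limma, adjusted p = 0.000197). Its mean signal was 6.40 log2 in DA normal endothelium and 7.04, 8.37 and 9.73 log2 in allografts on days 2, 3 and 4, against 6.55 log2 in Lewis normal endothelium and 6.52, 6.72 and 6.53 log2 in isografts. No other gene passed on any day, and Ido1, with the largest difference on day 4, had 5.59 log2 (SE 1.03, adjusted p = 0.188). Interferon-gamma-induced genes had medians of -0.28, 0.63 and 1.71 log2 for this difference on days 2, 3 and 4, and 0, 1 and 7 of 14 were higher adjusted over the list alone. Over all genes 0, 0 and 0 of them passed (adjusted p of the group = 0.876, 0.281 and 0.0974 with an estimated correlation). MHC class II genes had medians of 1.91, 1.60 and 1.96 log2, with 6, 4 and 6 of 7 higher adjusted over the list alone (adjusted p = 0.0641, 0.148 and 0.0952 with an estimated correlation). T cell genes had medians of 0.39, 0.51 and 0.85 log2, with 0, 0 and 8 of 15 higher adjusted over the list alone (adjusted p = 0.338, 0.241 and 0.0974 with an estimated correlation). Macrophage genes had medians of 1.42, 0.10 and 0.43 log2, with 13, 0 and 1 of 18 higher adjusted over the list alone (adjusted p = 0.0641, 0.870 and 0.575 with an estimated correlation). The type I interferon group had medians of -0.91, -0.31 and -0.26 log2 (adjusted p = 0.0796, 0.508 and 0.726 with an estimated correlation). No list passed on any of these days with an estimated correlation. By limma, 0, 0 and 1 genes passed on days 2, 3 and 4, and 480, 334 and 783 had an unadjusted p under 0.05, where 711 would by chance. With array weights the counts were 4, 2 and 187 (4, 1 and 6 with weights estimated gene by gene), with an intensity-trended robust prior 0, 0 and 1, and on the 4 groups alone 0, 3 and 2. The day 4 count of 1 became 81 without allograft day 4 replicate 1. For the direct difference between the grafts, which holds the strain difference too, the counts were 125, 150 and 321.

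Across genes, which are not independent, the changes of both graft types ran together, with Pearson's r of 0.769, 0.727 and 0.782 and Spearman's rho of 0.593, 0.493 and 0.594 on days 2, 3 and 4. Genes called in the same direction in both graft types numbered 178, 162 and 354, and 0 were called in opposite directions, against 6.80, 4.73 and 30.03 in the same direction for independent lists. Gpnmb, Lyz2, Selp and the vessel gene Plvap were among the transcripts that rose in both.

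From day 2 to day 4 the allograft preparations gained interferon-gamma-induced transcripts, in a comparison that asks how the endothelium changed as the graft response progressed. Ido1 rose by 4.69 log2 between these days (SE 0.73, adjusted p = 0.00363), and the transcription factor Batf2 by 3.32 log2. The guanylate-binding proteins Gbp4 and Gbp7, which act against microbes inside cells, rose by 3.23 and 2.58 log2. Sectm1b rose by 2.69 log2 (SE 0.26, adjusted p = 2.43e-05), and Ubd, a ubiquitin-like modifier, by 2.53 log2. These calls rest on the spread pooled over all groups. With the spread taken from the 2 compared groups alone, limma called neither Sectm1b (adjusted p = 0.999) nor any other gene. Of the 14 interferon-gamma-induced genes, 6 rose and 0 fell (12 rose adjusted over the list alone). Their median was 2.28 log2 (adjusted p = 0.0265 with an estimated correlation). Of the 16 MHC class I and processing genes, 5 rose (15 adjusted over the list alone), with a median of 1.14 log2 (adjusted p = 0.0306 with an estimated correlation). Nlrc5 rose by 2.19 log2 and Tap1 by 1.96 log2. Type I interferon-induced genes had a median of 1.17 log2, and 1 of 21 rose (19 adjusted over the list alone; adjusted p = 0.0683 with an estimated correlation). Complement genes that rose were 2 of 8, C1r at 1.49 log2 and Serping1 at 1.73 log2 (adjusted p of the group = 0.108 with an estimated correlation). Markers of other cells had medians in allografts over the same time of 0.64 log2 for T cell, 0.64 log2 for cytotoxic lymphocyte and 0.63 log2 for mural genes, which belong to smooth muscle and pericytes. Of these 0 of 15, 0 of 11 and 1 of 12 rose (4, 2 and 2 adjusted over the list alone), and the lists passed with the preset correlation only (adjusted p = 0.189, 0.226 and 0.108 with an estimated correlation). With the preset correlation only, MHC class II (median 1.42 log2), pan-leukocyte (0.38 log2) and macrophage genes (0.22 log2) passed as higher too. Neutrophil genes passed in this way as lower (-0.37 log2). In isografts the gains from day 2 to day 4 were the complement starter genes C1qa at 2.68 log2 and C1qc at 2.13 log2, Cfd at 2.79 log2, the macrophage receptor Adgre1 at 2.40 log2 and Rarres1 at 1.59 log2. All 5 were at least 2-fold higher in graft leukocytes. Of the 18 macrophage genes, 3 rose in isografts over this time (17 adjusted over the list alone). Their median was 1.33 log2 (adjusted p = 0.0163 with an estimated correlation).

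Between day 2 and day 4 limma called 54 genes higher and 0 lower in allografts, with 469 lower at an unadjusted p under 0.05, and 46 of the 54 were also higher on day 4 than in DA normal endothelium. Graft leukocytes held 4 of the 54 (7.41%) at a level at least 2-fold above allograft endothelium, against 8.64% of all genes. Since leukocytes had to exceed all allograft arrays, those of day 4 included, genes chosen as high on day 4 could hardly meet this. The share therefore does not tell their source. In isografts 5 genes were higher and 0 lower, with 126 lower at an unadjusted p under 0.05. The rise in allografts exceeded that in isografts for Sectm1b, by 2.68 log2 (SE 0.37, adjusted p = 0.00662), and for no other gene. As a group the interferon-gamma-induced genes rose more in allografts, with a median difference of 2.07 log2 (0 of 14 over all genes and 11 adjusted over the list alone; adjusted p = 0.0280 with an estimated correlation and 0.0985 by fry). In this difference 345 genes had an unadjusted p under 0.05, and array weights gave 28 genes (2 estimated gene by gene). The allograft count was 28, 21 and 15 without day 2 replicate 2, day 4 replicate 2 and day 4 replicate 3, 506 without day 4 replicate 1, 8 without the 2 arrays richest in fibroblast transcripts, 1668 with array weights (506 of them lower; 434 with weights estimated gene by gene) and 0 on the 2 groups alone. The count of the difference was 40 without allograft day 4 replicate 1, and the isograft count was 2, 17 and 1 without day 2 replicates 1, 2 and 3 and 1, 9 and 1 without day 4 replicates 1, 2 and 3. With an estimated correlation the interferon-gamma and MHC class I calls in allografts were lost without day 2 replicate 3 (adjusted p = 0.200 and 0.303) and without day 4 replicate 2 (0.0652 and 0.0682). The isograft macrophage call was lost without day 2 replicate 1 (0.0740) and day 4 replicate 1 (0.110), and the interferon-gamma call of the difference without allograft day 2 replicate 3 (0.0641), allograft day 4 replicate 2 (0.0998), isograft day 2 replicate 2 (0.0742) and isograft day 4 replicates 1 and 3 (0.0524 and 0.0863).

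**Figure D3:**
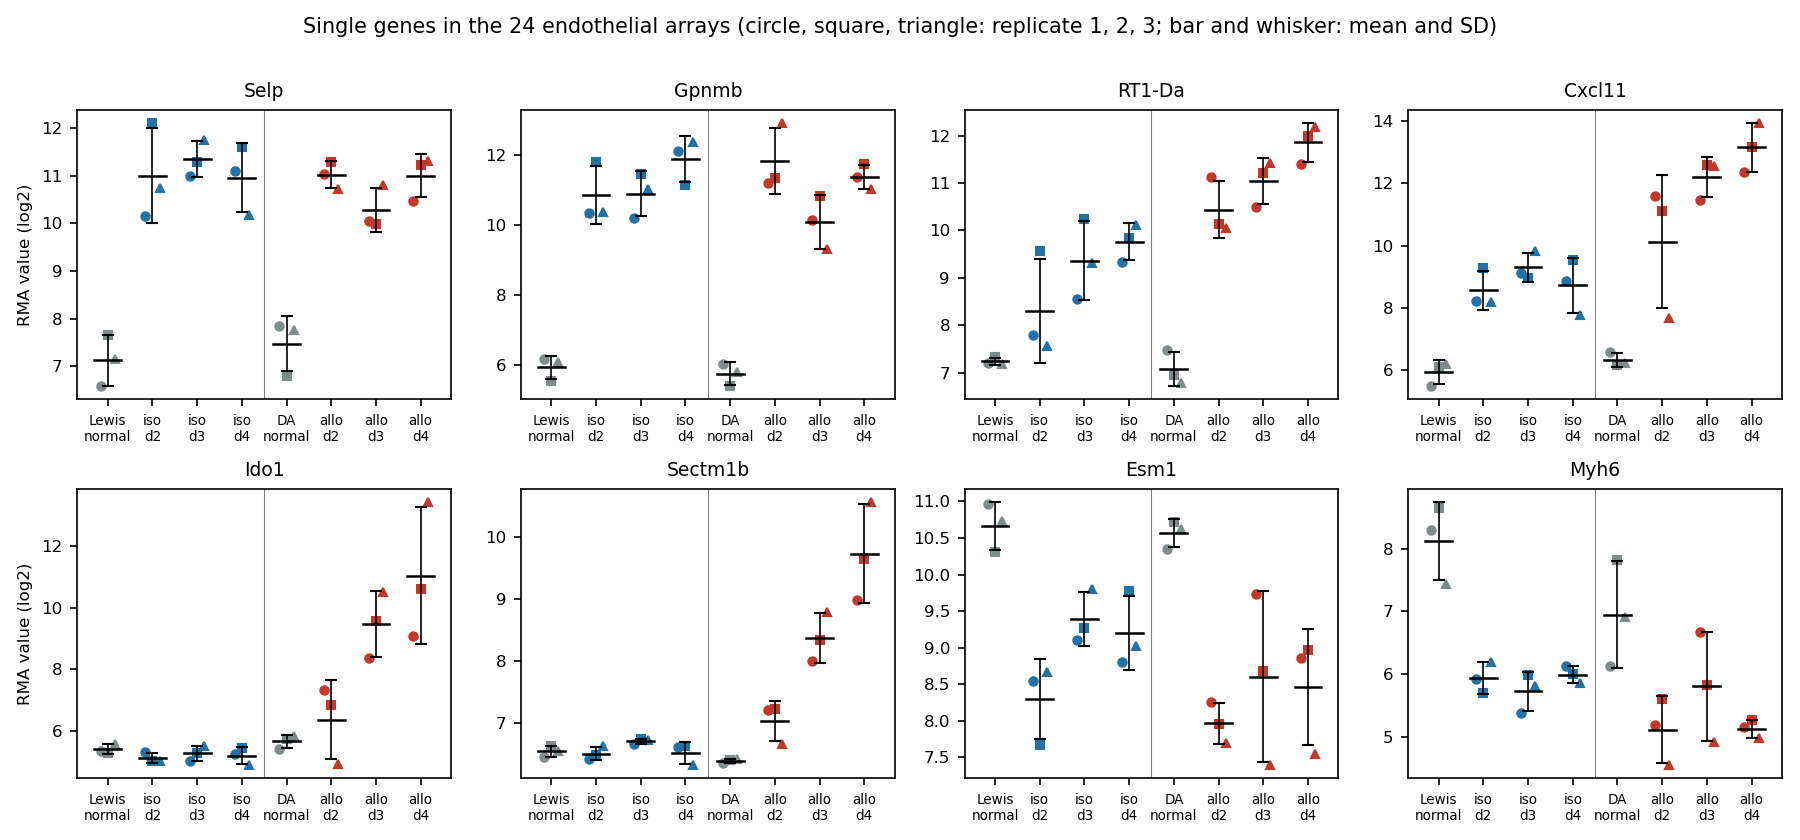
Each panel shows the RMA signal (log2) of 1 gene (Selp, Gpnmb, RT1-Da, Cxcl11, Ido1, Sectm1b, Esm1 and Myh6) on every endothelial array for normal hearts and days 2, 3 and 4 of isografts and allografts. Circles, squares and triangles are replicates 1, 2 and 3, bars are means and whiskers are SD (n = 3), and Sectm1b goes from 6.40 in DA normal endothelium to 9.73 in day 4 allografts while isografts stay between 6.52 and 6.72.

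Normal endothelium of DA and Lewis rats was compared because the strains provide the baselines of both graft types. MHC class I genes, which are highly polymorphic between strains, differed in both directions, with RT1-T24-4 higher in DA by 3.43 log2 (SE 0.15, adjusted p = 6.88e-12), RT1-CE16 higher by 2.94 log2 and RT1-A3 at -1.60 log2. The antiviral genes Ifit1 and Ifi27l2b were higher in DA by 3.67 and 3.23 log2, and the matrix signal protein Ccn1 by 5.01 log2 (SE 0.57). Higher in Lewis were the RNA methylation factors Wtap at -3.30 log2 and Ythdf2 at -3.21 log2, and the iron-trapping protein Lcn2 at -3.18 log2. Of the 16 MHC class I and processing genes, 2 were higher and 1 lower in DA (3 and 1 adjusted over the list alone; adjusted p = 0.693 with an estimated correlation). Of the 21 type I interferon-induced genes, 1 was higher (6 adjusted over the list alone) and 19 had a positive difference. Their median was 0.47 log2 (adjusted p = 0.488 with an estimated correlation). Cardiomyocyte genes were lower in the DA preparations, 7 of 18 (12 adjusted over the list alone). Their median was -0.99 log2, with troponin T (Tnnt2) at -2.27 log2 (adjusted p of the list = 0.169 with an estimated correlation). By limma 144 genes passed, 69 higher and 75 lower in DA, and no list passed with an estimated correlation. The count was 93 and 75 without DA replicates 1 and 2, 83 without Lewis replicate 2, and 554 with array weights (474 estimated gene by gene). A probe can bind the transcript of 1 strain better, and the comparison shares its DA arrays with the allograft comparisons and its Lewis arrays with the isograft comparisons.

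Graft leukocytes were set beside allograft endothelium to see which transcripts mark leukocytes from the same kind of graft. The leukocyte arrays held the phagocyte gene Fcnb at 6.31 log2 over endothelium, the chemokine receptor of inflammatory monocytes Ccr2 at 5.44 log2, and the RNA-sensing receptor Tlr7 at 5.13 log2. Gpr34, Clec4a, Tlr1, Epsti1 and Tifab lay between these, at 5.44, 5.25, 5.25, 5.19 and 5.19 log2. The endothelial arrays held Reg3g (-5.41 log2) and Coch (-4.76 log2) with the largest differences. After these came the lymphatic chemokine Ccl21 (-4.57 log2), the mesenchymal cadherin Cdh11 (-4.45 log2) and Reg3b (-4.39 log2). Prss23 (-4.37 log2), the vessel protein Mmrn1 (-4.35 log2) and H19 (-4.33 log2) followed. Every measured macrophage, T cell and cytotoxic lymphocyte gene (18, 15 and 11) was at least 2-fold higher in leukocytes, and so were 16 of 17 pan-leukocyte genes, 8 of 11 neutrophil genes and 2 of 7 B cell genes. All 18 endothelial markers were at least 2-fold higher in endothelium, with a median of -3.23 log2, and so were 8 of 15 adhesion genes and 10 of 17 angiogenesis and Notch genes. The interferon-gamma-induced genes had a median of 0.12 log2, with 1 of 14 at least 2-fold higher in leukocytes. In all, 1229 genes were at least 2-fold higher in leukocytes and 1282 in endothelium without overlap between the 4 and the 9 arrays, which chance order would give for 0.280% of genes. Both sets of arrays were normalized apart, so these values are levels after removal of a median shift of 0.334 log2 and carry no test.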

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

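Of the tests in this part, the one of whether isografts share the interferon-gamma response to the same size was chosen only after the result was seen, and so was leaving out the 2 fibroblast-rich allograft arrays.

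The change in allografts differed from that in isografts for 1 gene on day 4, Sectm1b, by 3.35 log2 (SE 0.37, limma, adjusted p = 0.000197). It differed for 1 gene between day 2 and day 4 as well, again Sectm1b, by 2.68 log2 (adjusted p = 0.00662). Graft leukocytes held Sectm1b at 7.04, 7.40 and 7.97 log2 on days 2, 3 and 4, as deposited, below the 8.37 and 9.73 log2 of allograft endothelium on days 3 and 4. The day 4 difference of Sectm1b passed in each of the alternatives run, with each of the 12 arrays left out too, at values from 2.94 (without allograft day 4 replicate 3) to 3.73 log2 (without allograft day 4 replicate 1). The day 2 to day 4 difference of Sectm1b did not pass on the 4 groups alone (2.68 log2, adjusted p = 0.642) or without the 2 fibroblast-rich arrays (2.54 log2, adjusted p = 0.0953). In both settings the difference stayed near its value. Whether these calls were lost to the smaller number of arrays or to a larger spread within the compared groups was not tested. Over its other alternatives the adjusted p ran from 1.01e-05 to 0.0411. As a list, the interferon-gamma-induced genes rose more from day 2 to day 4 in allografts than in isografts, by a median of 2.07 log2. The list passed by camera (adjusted p = 0.0280 with an estimated correlation) but not by fry.

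The genes that were higher in allograft endothelium on day 4 than on day 2 may reflect a growing interferon-gamma response to the mismatch, or come from leukocytes or from 1 array. More leukocyte RNA on day 4, in the mix of the measured leukocytes, is argued against. The added share of 2.15% from pan-leukocyte transcripts accounted for at least 50% of the rise in 0 of the 54 genes, and for a median of 2.02%. The upper exact 95% limit of 6.60% takes the genes as independent, which they are not. From day 2 to day 4 the T cell share went from 5.39% to 14.7% and the neutrophil share from 7.65% to 1.17%. A change of the leukocyte mix is therefore not covered. The lowest median rise of these genes with 1 array left out was 1.18 log2 (without allograft day 4 replicate 3), against 1.52 log2 with all. This cannot decide about a single array, since the genes were called on these same 6 arrays. Their number ran from 15 (without day 4 replicate 3) to 506 (without day 4 replicate 1). The interferon-gamma list, fixed beforehand, kept a median rise of at least 1.76 log2 with 1 array left out. By camera it did not pass without day 2 replicate 3 (adjusted p = 0.200 with an estimated correlation) or day 4 replicate 2 (0.0652). The interferon-gamma list rose by a median of 2.28 log2 in allografts and 0.19 log2 in isografts, a median difference of 2.07 log2. With 1 array left out the difference ran from 1.60 to 2.50 log2. These medians lean against a response of the same size in isografts but do not settle it. Camera gave an adjusted p of 0.0280 with an estimated correlation, but it sets the list against the other genes. By fry, which tests the list by itself, the difference did not pass. On fewer arrays camera passed in 7 of 12 sets (highest adjusted p 0.0998, without allograft day 4 replicate 2). A smaller shared response stays open too, since 12 of 14 members had positive values in isografts against 13 in allografts. Without the 2 fibroblast-rich arrays 8 genes passed on fewer arrays, while the median rise of the 54 genes was 1.36 log2.

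Other splits of the same arrays were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and the real split was the 1 with the most genes for strain (144 against at most 0 in the others), isografts on day 2 (211 against 1), day 3 (360 against 0) and day 4 (450 against 0), allografts on day 2 (850 against 18), day 3 (324 against 2) and day 4 (1627 against 1), and isografts between day 2 and day 4 (5 against 0). For allografts between day 2 and day 4, 2 of the 10 splits gave at least 54 genes, the other 1170. That split set day 2 replicates 1 and 2 and day 4 replicate 1 against day 2 replicate 3 and day 4 replicates 2 and 3, and points to a structure of the samples other than the day. By list medians, which carry no test here, the second set held more fibroblast (1.70 log2), matrix (1.02), macrophage (0.84), lymphatic (0.75), complement (0.73), pan-leukocyte (0.71), interferon-gamma-induced (0.69) and MHC class II transcripts (0.68 log2). It held fewer of lipid uptake (-0.65 log2). MHC class I, chemokine and erythroid medians came next, at 0.55, 0.54 and -0.55 log2. For the differences of changes on days 2 and 3 the real count was 0, which 100 of 100 splits reach whatever the data (highest other 0), so the splits say nothing there. For day 4, 3 of 100 splits gave at least 1 gene (highest other 1), a share under 0.05 in this draw. It rests on a count of 1 gene that other splits reached too, so it does not exclude chance. For day 2 to day 4, 8 of 100 splits gave at least 1 gene (highest other 8), so chance is not excluded there either.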

How the results depend on the processing

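Leaving out the fibroblast-rich arrays, the pan-leukocyte covariate, array weights estimated gene by gene and the comparison of leukocyte levels in place of the planned test were chosen only after the data were seen. Median centring, quantile normalization, leaving out the lowest 30% of genes, the mean of a gene's probe sets, the trended robust prior, all 28 arrays, the replicate block and leaving out strain-different genes kept each count within 1.5 times its value. With the replicate number as a block, the counts other than that of day 2 isografts, where only a number is shared, were 166 for strain, 433 and 504 for isografts on days 3 and 4, 1050, 362 and 1889 for allografts on days 2, 3 and 4, 0, 0 and 1 for the differences of changes, and 5, 51 and 1 between day 2 and day 4 for isografts, allografts and their difference. Every probe set gave 359 for strain and 4652 for the comparison of leukocyte levels (2511 in the main setting). Array weights, which give noisy arrays less weight, gave 554 for strain, 451, 1591 and 886 for isografts on days 2, 3 and 4, 1937, 789 and 4870 for allografts, 4, 2 and 187 for the differences of changes, 41, 1668 and 28 between day 2 and day 4, and 11094 for the planned leukocyte test (9931 without weights). The estimate of these weights stopped before it converged, and with weights estimated gene by gene the counts were 474 for strain, 418, 1318 and 827 for isografts, 2187, 762 and 3000 for allografts, 4, 1 and 6 for the differences of changes, 35, 434 and 2 between day 2 and day 4, and 10421 for the planned leukocyte test. A 2-fold minimum left 77 genes for strain, 122, 214 and 267 for isografts and 363, 213 and 657 for allografts, by its construction. On the compared groups alone, with fewer arrays to estimate the spread, the count was 510 and 514 for allografts on days 2 and 4, and 1, 0 and 0 between day 2 and day 4. In the same setting it rose to 562 for isografts on day 3 and to 3 and 2 for the differences on days 3 and 4. The cause of these rises was not tested. The direct difference of the grafts, which adds the strain difference, gave 125, 150 and 321. Without leukocyte-enriched genes, fewer genes being tested, allografts had 494 on day 2 and 121 on day 3. The balance of direction in day 2 allografts, 502 higher and 348 lower in the main setting, was 434 and 426 with median centring, 675 and 321 with quantile normalization and 628 and 612 with every probe set. Without the fibroblast-rich arrays the count was 439 for day 2 allografts, 8 for allografts between day 2 and day 4 and 0 for the difference of these changes. With the pan-leukocyte covariate, which nearly separates grafts from normal hearts, it was 65, 41 and 34 for isografts, 3, 1 and 0 for allografts and 3 for isografts between day 2 and day 4. The planned leukocyte test called 9931 genes, and 9953 with a trended robust prior, against the 2511 genes of the level comparison. Where no construction is named, the cause was not tested. With 1 array left out the counts ran from 75 to 132 (strain), 92 to 176, 150 to 300 and 246 to 391 (isografts), 421 to 833, 168 to 322 and 862 to 2606 (allografts), 0 to 0, 0 to 0 and 1 to 81 (differences of changes), 1 to 17, 15 to 506 and 1 to 40 (day 2 to day 4), and 2451 to 2749 (leukocyte levels), on fewer arrays.

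Over 1624 values of named genes and 35640 alternatives, 33831 kept their side of the threshold, 1074 no longer passed, 709 came to pass and 26 reversed. A change of sign counted as reversed only where the value passed in the main setting or the alternative. Changes of sign among values that passed in neither were not counted. Of 403 called values, 515 of 2430 alternatives with 1 array left out no longer passed, with 101 of 403 on the compared groups alone and 5 and 6 with the 2 estimates of array weights. With the covariate 280 of 384 no longer passed and 23 reversed, and without the fibroblast-rich arrays 43 of 176 no longer passed. Of 491 alternatives for 26 lists, 452 moved by less than the spread between replicates, 39 by more and 0 reversed. Reversed were Flt4 between day 2 and day 4 in allografts with array weights (0.50 log2), and with the direct difference Cdkn1a on day 2 (-1.83 log2) and Lcn2 on day 4 (-2.79 log2), which hold the strain difference. With the covariate, day 2 allografts reversed for Ccl2 (-0.38), Cd3g (-0.59), Cd8a (-0.069), Csf3r (-0.52), S100a8 (-0.77) and S100a9 (-0.47), day 3 for Il1b (-0.19), Ccl3 (-0.30), Ccl7 (-0.12), Hmox1 (-0.11) and Cd3g (-0.031), and day 4 for Il1b (-1.09), Ccl2 (-0.33), Ccl4 (-0.46), Cxcl2 (-0.63), F3 (-0.36), Arg1 (-0.99), Spp1 (-0.041), Casp4 (-0.050), Tek (0.080), Cd5 (-0.018), Klrd1 (-0.068) and Pf4 (-0.16 log2). Signals near the background limit what dim genes can show, and the filter on them moved no count by over 1.5 times.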

Other observations

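Of the tests in this part, those of a lost endothelial share, of the neutrophil share and of strain-dependent probe binding were chosen only after the result was seen, and so was the pan-leukocyte covariate.

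Single genes of stress and metabolism passed in both graft types, and none of their lists did with an estimated correlation on day 4. The metal-binding protein Mt2A rose by 2.51, 2.58 and 2.41 log2 in isografts and 3.43, 2.69 and 3.12 log2 in allografts on days 2, 3 and 4, and the heme-degrading enzyme Hmox1 by 1.54 and 2.56 log2 in isografts on days 3 and 4 and 2.21, 1.54 and 2.47 log2 in allografts. Of 12 oxidative and heat stress genes, 1, 2 and 2 rose in isografts and 2, 2 and 3 in allografts, where 0, 0 and 1 fell (on day 4 2 and 5 rose adjusted over the list alone; adjusted p = 0.370 and 0.404 with an estimated correlation). The glycolysis enzyme Pgk1 rose by 0.75, 0.94 and 0.84 log2 in isografts and 1.06, 0.75 and 1.35 log2 in allografts, and in allografts Pfkfb3, an activator of glycolysis in endothelium, by 1.70 and 2.00 log2 on days 3 and 4. Of 15 hypoxia and glycolysis genes, 1, 2 and 2 rose in isografts and 2, 2 and 5 in allografts (on day 4 3 and 6 adjusted over the list alone; adjusted p = 0.527 and 0.208 with an estimated correlation). Among 11 lipid uptake genes of cardiac capillaries, 0, 1 and 0 fell in isografts and 1, 0 and 3 in allografts, with Fabp5, a fatty acid carrier, at -0.90 log2 on day 4 (on day 4 0 and 6 fell adjusted over the list alone; adjusted p = 0.527 and 0.0933 with an estimated correlation). Among 11 coagulation genes, 1, 1 and 2 rose in isografts and 1, 0 and 3 in allografts, where 0, 0 and 2 fell (adjusted over the list alone 4, 5 and 5 rose in isografts and 2, 0 and 4 in allografts; adjusted p on day 4 = 0.172 and 0.329 with an estimated correlation). Procr, the receptor that speeds the anticoagulant protein C, rose by 1.12, 1.25 and 1.08 log2 in isografts, and tissue factor (F3), the starter of clotting, by 1.38 log2 in allografts on day 4. Among 12 vasoregulation genes, 1 rose on each day in isografts, and 3, 0 and 3 rose and 2, 2 and 3 fell in allografts, with the flow-sensing factor Klf4 at -0.75 and -0.87 log2 on days 3 and 4 (adjusted over the list alone 2, 1 and 1 rose in isografts and 3, 3 and 4 in allografts; adjusted p on day 4 = 0.583 and 0.963 with an estimated correlation). Of 23 proliferation genes, 0 rose on each day in isografts and 1, 0 and 0 in allografts (adjusted over the list alone 0 rose on each day in isografts and 1, 0 and 0 in allografts; adjusted p on day 2 = 0.422 and 0.532 with an estimated correlation). Of 15 cell death genes, 0 rose on each day in isografts and 0, 0 and 2 in allografts, with Bid, which passes death signals to mitochondria, at 1.72 log2 on day 4 (adjusted over the list alone 0, 0 and 1 rose in isografts and 1, 1 and 3 in allografts; adjusted p on day 4 = 0.947 and 0.301 with an estimated correlation).

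Of 5 platelet genes, 0, 1 and 1 rose in isografts and 2, 0 and 2 in allografts, with the chemokine Pf4 at 1.72 and 2.55 log2 on days 3 and 4 of isografts and 2.35 and 2.40 log2 on days 2 and 4 of allografts (adjusted over the list alone 0, 1 and 1 rose in isografts and 2, 2 and 2 in allografts; adjusted p on day 4 = 0.715 and 0.126 with an estimated correlation). Of 12 mural genes, which belong to smooth muscle and pericytes, 3 rose in day 4 allografts, and the smooth muscle kinase Mylk fell to -0.68 and -0.72 log2 in isografts on days 2 and 3 and -0.68 log2 in allografts on day 2 (4 rose adjusted over the list alone; adjusted p on day 4 = 0.947 and 0.208 with an estimated correlation). Of 9 fibroblast genes, 0 rose on each day in isografts and 0, 0 and 1 in allografts, Thy1 by 1.56 log2 on day 4 (adjusted over the list alone 0 rose on each day in isografts and 0, 1 and 1 in allografts; adjusted p on day 4 = 0.621 and 0.354 with an estimated correlation). Lymphatic genes that rose in allografts were 2, 1 and 1 of 4, with Pdpn at 3.00 and 2.65 log2 on days 2 and 4 (2, 1 and 2 adjusted over the list alone; adjusted p = 0.273, 0.529 and 0.272 with an estimated correlation). B cell genes (7 measured) gave 0 rises on each day in isografts and 0, 0 and 1 in allografts (adjusted over the list alone 0 rose on each day in isografts and 0, 0 and 1 in allografts; adjusted p on day 4 = 0.715 and 0.549 with an estimated correlation), and erythroid genes (4 measured) gave 0 rises in both graft types (adjusted p on day 4 = 0.777 and 0.873). In isografts, angiogenesis and Notch genes gave 2, 1 and 1 falls and 1, 2 and 1 rises of 17 (3, 4 and 4 fell and 2 rose on each day adjusted over the list alone; adjusted p = 0.167, 0.358 and 0.527 with an estimated correlation), while type I interferon genes (21), MHC class I genes (16), cytotoxic lymphocyte genes (11) and neutrophil genes (11) gave 0 rises and 0 falls on each day by limma (adjusted p on day 4 = 0.864, 0.614, 0.947 and 0.864 with an estimated correlation).

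Macrophage transcripts were higher in the endothelial preparations of both graft types although cells with CD45 had been removed. Leukocytes of the graft carried along as a whole would bring the transcripts of each leukocyte type in 1 proportion. On day 4 in allografts the neutrophil transcripts went against this as the whole cause. The share that macrophage transcripts imply was 9.22 times theirs (10.8% against 1.17%). The ratio was at least 3.54 over all leukocyte profiles and with 1 array left out. Of the 11 neutrophil genes, 8 were at least 2-fold higher in graft leukocytes. T cell, B cell, pan-leukocyte and cytotoxic lymphocyte transcripts implied day 4 shares of 14.7%, 8.46%, 8.29% and 4.70%, nearer to that of macrophages. Of the 7 B cell genes only 2 were at least 2-fold higher in graft leukocytes, so their share measures leukocyte RNA poorly. Carry-over of the whole mix therefore stays open in allografts on days 2 and 3, and on day 4 as part of the cause. The macrophage to neutrophil ratio was 1.02 on day 2 and 3.11 on day 3 (lowest 1.90), and that of macrophage to cytotoxic lymphocyte transcripts 6.36, 1.34 and 2.29 on days 2, 3 and 4 (lowest 1.30, 0.580 and 1.06). The macrophage to T cell ratio was at most 1.44 (day 2, 0.773 to 1.97 with 1 array left out), with 0.481 on day 3, outside the 2-fold range set for it, and 0.733 on day 4. In isografts, whose leukocytes were not measured, the list means over Lewis normal hearts were 1.57 ± 0.62, 2.36 ± 0.55 and 3.02 ± 0.44 log2 for macrophage genes on days 2, 3 and 4 but 0.31 ± 0.31, 0.44 ± 0.30 and 0.39 ± 0.03 log2 for T cell genes (SD, n = 3). A lower endothelial share with an unchanged mix of the other cells is argued against as the whole cause in both graft types. It would raise the markers of every other cell type alike. In isografts cardiomyocyte genes lay at -0.83 log2 or lower on each day (at most -0.53 log2 with 1 array left out). Part of this fall may rest on the Lewis baseline, as normal DA hearts lay at -0.99 log2 against normal Lewis hearts. The isograft mural medians were 0.15, 0.13 and 0.05 log2 and the fibroblast medians 0.15, 0.17 and 0.29 log2. The isograft macrophage medians were 1.66, 2.34 and 3.04 log2. In allografts the macrophage median stood at least 2.05 log2 above the highest of the cardiomyocyte, mural and fibroblast medians (1.88 log2 with 1 array left out). A partial loss stays open in day 4 allografts, where the mural and fibroblast medians were 0.57 and 0.93 log2, the endothelial median was -0.32 log2 and the cardiomyocyte median -0.41 log2. A change of macrophages in the graft, or of cells that carry CD31 and macrophage transcripts, may contribute and was not tested apart.

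Type I interferon-induced transcripts were lower in day 2 allografts than in DA normal endothelium. By camera the list passed with the preset correlation only (adjusted p = 0.0804 with an estimated correlation). A single DA normal array is argued against (-1.10 log2 at the nearest to 0, against -1.23 with all), and so is a single day 2 array (-0.87 log2 without replicate 3). The list lay at -0.35 log2 in allografts against isografts on day 2 and at 0.47 log2 in normal DA against Lewis hearts, which restates the fall and does not test probe binding, as both groups of the pattern are DA hearts. Normal DA hearts that were all high before any graft may account for part of it and stay open, since the same 3 arrays serve both comparisons, and the difference from isografts had an adjusted p of 0.0796 with an estimated correlation.

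Recipient RNA in the allograft preparations was looked for with 7 transcripts high in Lewis and low in DA normal endothelium, which reached a median of 7.30% of the Lewis level on day 4, 11.2% on day 2 and 2.78% on day 3. The 14 transcripts high in DA and low in Lewis had lost a median of 16.4% of their excess on day 4, 35.7% on day 2 and 20.1% on day 3. Recipient cells had been expected to bring at least 10% in both sets and their absence under 5%. On day 4 the loss of DA transcripts lay above the first limit, and the Lewis value lay between both limits. Both sets were chosen by their difference in the same DA normal arrays that form the baseline. Part of both values can therefore arise without recipient cells, and the question stays open.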
